A study of Drosophila melanogaster with 3 samples.

How the data were processed

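Anti-GFP ChIP-seq was carried out on 3 biological replicates of whole embryos, 0 to 18 h old, from flies with an ase-eGFP transgene. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and a control experiment belongs to the series. The control's own values were not used here. The replicate numbers are those in the labels, and the labels call them biological replicates. The genome assembly is dm6, per the labels.

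The deposited files are peak lists. Per the text records deposited with them, each replicate's lists derive from that replicate's alignments and the control, and the 4 pairs of series-wide lists from the alignments of all 3 replicates and the control. Which replicates each series-wide pair sets against each other is not stated there and was not inferred. The aligner, the peak caller and their versions are not given in the sources used here. Each line gives a peak's interval, the distance from its start to its summit, a score and a signal. The score in the deposited lists is the authors' IDR score, at most 1000, which falls as the global IDR rises. The signal in the deposited lists is the authors' peak strength against the control, and it was used only to order or describe peaks within a list. The ranked lists as deposited also hold the −log10 of the global IDR, from which stricter thresholds were set. Thresholded lists keep peaks with a global IDR of 0.01 or less, and derive from 1 more file than the ranked lists, which is not described in the sources used here. Each thresholded series-wide list was set beside the ranked list that holds all of its peaks with the same scores.

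The lists carry no counts or coverage. The depth of each replicate is therefore unknown, no interval that needs it was given, and differences between replicates in the number of peaks cannot be set against depth. Peaks are neighbours in the genome and share chromatin, so p-values from tests over peaks measure the spread over peaks of a replicate. The agreement of the 3 replicates was therefore required for a call: a result on location or sequence was called only when each replicate passed p of 0.05 in the same direction. Samples could not be paired between conditions because the series has a single group. The comparison of summits with flanks of the same peaks used Fisher's exact test, which ignores that they are paired.

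Summits were placed on the annotation of Ensembl release 115 (BDGP6.54) and on the RefSeq sequence of the same assembly. The peak ends were checked against the chromosome lengths. Tests of location, sequence and genes used the 6 arms 2L, 2R, 3L, 3R, 4 and X, which left out 1, 5 and 108 thresholded peaks of replicates 1, 2 and 3. Transcription starts were those of all transcripts of the 13945 protein-coding genes on these arms. Peaks that passed were compared with the ranked peaks of the same replicate that did not pass, with two-sided Fisher's exact tests. The overlap of replicates was compared with 10000 random draws from the ranked list. Motifs were searched on both strands within 50 bp of the summit: the 10 E-boxes CANNTG, all of them together, TATCGATA, GAGAGAG, CAGGTAG and YGTGRGAA. All 2080 6-mers were tested in each replicate with Benjamini-Hochberg adjustment, and counted when the adjusted p was under 0.05 in the same direction in all 3. Backgrounds matched on GC content took up to 5 peaks that did not pass for each peak that passed, with the same number of G and C bases in the window. The mean GC content of the matched peaks was 34.9%, against 34.1% in those that passed, because very AT-rich peaks are rare in the background.

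For gene lists, a protein-coding gene had a peak when a conservative summit lay within 1 kb of any of its transcription starts. The background was the genes with any ranked peak within that distance. The 12 lists, the tests and the alternatives were fixed before the data were examined. Older symbols in the lists were matched to current ones (Dl to Delta, fas1 to Fas1, Cg25C to Col4a1). Genes named in the text were chosen by a rule fixed at the same time: ase, the gene nearest to each of the 20 strongest conservative peaks, and from each list up to 5 genes with a conservative peak found in all 3 replicates, by signal. For 6-mers it was the 10 with the largest mean odds ratio in each direction. Other members with a peak are named beside small counts and were chosen after their values were seen. The windows from 100 to 150 bp beside the summit and the stretches of 100 kb were also chosen after the data were seen. Of 4 further gene lists added then, those of mitochondrial ribosomal protein and translation initiation factor genes were chosen because members had been seen among the strongest peaks, and those of proteasome and Hox genes before their own values were seen.

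The alternatives were a stricter IDR, each replicate left out, other definitions of overlap, the other series-wide lists, other distances to a TSS, other windows and backgrounds for motifs, and other ways to assign peaks to genes. The planned stricter threshold, a global IDR of 0.01, turned out to be the authors' own, and 0.001 was added after the data were seen. Also added then were CAGCTG in peaks near and far from a TSS, an unmatched background for 6-mers as large as the matched one, and the share on X with peaks counted as passed that reached the threshold score but are not in the thresholded lists.

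The tests were tried on simulated data first. In replicate 1, each of 20 6-mers planted in 10% of 2438 windows drawn from peaks that had not passed was recovered, and 0 of 2080 were called with none planted. Both sets of windows were random draws from peaks that had not passed, so they shared GC content and position. The 0 calls therefore say nothing on calls that follow from the differences in these between passing and other peaks. In 100 simulations of the gene list test with random lists, 4 of 1200 lists were called. A list of 92 genes of which 46 had a peak was called in 100 of 100 simulations, and a list of 10 genes of which 5 had a peak in 0 of 100, so short lists can be called only at larger shares. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.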

Results

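Asense (ase) is a basic helix-loop-helix (bHLH) transcription factor of the achaete-scute complex that is made in neuroblasts, the neural stem cells of the fly, and in sensory organ precursors. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of 0 to 18 h that carry an ase gene fused to eGFP, with an antibody against GFP. The data comprise 3 biological replicates of a single group, so that no condition was compared with another. Each replicate has a list of all peaks ranked by the irreproducible discovery rate (IDR) and a shorter list of the peaks that passed the authors' threshold, a global IDR of 0.01. For the whole series, 4 further pairs of lists were made from all 3 replicates, and the authors call 1 of them conservative. Peak signals are the authors' own and were used only to order peaks within a list. Peak lists hold no read counts, so the sequencing depth of each replicate is unknown.

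Most of the strongest peaks lay close to transcription start sites. All positions are on dm6, with summits and intervals counted from 1. The highest conservative peak, on 2L from 6612563 to 6612882, had a signal of 2117 and its summit lay in an intron of CG11050 (FBgn0031836), 1039 bp from the nearest annotated transcription start site (TSS). It was followed by an intergenic peak 94 bp from the TSS of CG14100 (3L, 19590468 to 19590768, signal 1913) and by one 30 bp from the TSS of Ugalt, a UDP-galactose transporter gene (X, 2703745 to 2704024, signal 1782). The summit of the peak at mRpL41, a mitochondrial ribosomal protein gene, was intergenic and 139 bp from its TSS (2R, 15217603 to 15217909, signal 1681). Peaks at mRpS10 (3R, 15229412 to 15229667), mRpL23 (3L, 2373477 to 2373748), the complex I assembly gene CIA30 (3R, 29736715 to 29736981) and PNPase, for a mitochondrial RNA-processing enzyme (3R, 31404508 to 31404793), had signals of 1256, 1000, 1475 and 1263. The Polycomb group gene ph-p had an intronic summit 496 bp from an annotated TSS (X, 2137220 to 2137501, signal 1398), and the summit at Chro, which encodes a chromosomal and spindle protein, was in an untranslated exon 85 bp from the TSS (3L, 22878760 to 22879033, signal 1275). The summit 105 bp from the TSS of eIF6, a gene of large ribosomal subunit maturation, lay in an intron of the neighbouring gene ytr (2R, 23850291 to 23850521, signal 1129). The remaining nearest genes of the 20 strongest peaks were Tcs5, CenG1A, CG5611, CG13323, CG18549, Adf1, CG32772, px and Lamtor3. Of these 20 peaks, 17 had a summit within 1 kb of a TSS, 14 within 200 bp, and all 20 overlapped a thresholded peak in each of the 3 replicates. The peak nearest to CG13323 was 11921 bp from its TSS.

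Between 1812 and 2439 peaks passed the threshold in a replicate. Replicate 1 had 2439 of 85890 ranked peaks (2.84%), replicate 2 had 1877 of 102109 (1.84%) and replicate 3 had 1812 of 107984 (1.68%), a mean of 2043 ± 345 (SD, n = 3). The conservative list held 3227 of 140142 ranked peaks, and the other series-wide lists held 4209, 2329 and 2175. No test applies to these counts. At a global IDR of 0.001 the mean per replicate was 1276.

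Most thresholded peaks recurred in another replicate. Of the peaks of replicate 2, 81.6% overlapped a peak of replicate 1 by at least 1 bp, and 60.3% a peak of replicate 3. Of the peaks of replicate 1, 62.6% overlapped one of replicate 2 and 51.0% one of replicate 3, and for replicate 3 the values were 68.5% with replicate 1 and 62.3% with replicate 2. The mean over the 6 ordered pairs was 64.4%. Random draws of the same number of peaks from the ranked list gave between 1.66% and 2.42%, and none of 10000 draws reached the observed overlap in any pair (one-sided permutation p = 0.0001, the smallest these draws can give). The lists of all replicates were made with the control, and the draws do not account for agreement that a shared control could bring. Of the 3227 conservative peaks, 1039 (32.2%) overlapped a thresholded peak in all 3 replicates, 735 in 2, 719 in 1 and 734 in none. Recurrence followed signal: with the conservative peaks ordered by signal and split into 4 parts of about 806 peaks, 92.3% of the strongest part were found in all 3 replicates, and 32.9%, 1.99% and 1.73% of the following parts. The conservative signal comes from the alignments of the same 3 replicates, so a part of this gradient is built in.

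At the ase locus itself (FBgn0000137, X, 460747 to 463176, plus strand) peaks ranked in the lower part of the conservative list. A promoter peak with its summit at 460719, 28 bp from the TSS and inside an intron of the overlapping gene CG32816, was in the conservative list (460557 to 460880) with a signal of 95.6, rank 2340 of 3227. In the replicates' own lists it passed in replicate 2 alone, at a global IDR of 0.00718, and reached 0.201 in replicate 1 and 0.0930 in replicate 3. An upstream peak with its summit at 457231, 3516 bp from the TSS and in an intron of CG32816, was stronger (signal 124.7, rank 1707) and passed in all 4 series-wide lists but in none of the 3 replicates. In the replicates its global IDR was 0.0114, 0.642 and 0.0130.

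Peaks that passed were concentrated just upstream of transcription starts. Their summits lay within 1 kb of a TSS of a protein-coding gene in 58.6% ± 2.20 of cases (SD, n = 3), against 22.7% ± 3.04 of the ranked peaks that did not pass. The difference of 35.9 ± 1.23 percentage points had the same direction in 3 of 3 replicates, with odds ratios from 4.38 to 5.29 (two-sided Fisher's exact test in each replicate, highest p = 8.91e-240 of 3 tests). Among the summits within 1 kb, 79.3% ± 1.08 were upstream of the nearest TSS, against 40.1% ± 0.410 for peaks that did not pass, and the median distance was 151 ± 7.09 bp against 430 ± 9.04 bp (SD, n = 3). Coding exons beyond 1 kb held few passing peaks, 0.569% ± 0.0312 of all passing summits against 15.5% ± 0.905 of the others. Summits in introns and in intergenic sequence were likewise counted only beyond 1 kb of a TSS. Introns held 26.2% ± 0.553 of all passing summits and intergenic sequence 13.8% ± 1.85, against 34.6% ± 0.816 and 24.7% ± 3.32 of the others (Fisher's exact test, highest p = 7.34e-14 and 8.64e-31). The larger share near a TSS lowers these shares. They therefore do not show that passing summits beyond 1 kb avoid introns or intergenic sequence. Untranslated exons beyond 1 kb held 0.762% ± 0.204 of all passing summits and 2.51% ± 0.207 of the others. Beyond 1 kb, introns thus held most of the passing summits but only a minority of the others. Passing summits there were more often intronic, though this was not tested.

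**Figure D1:**
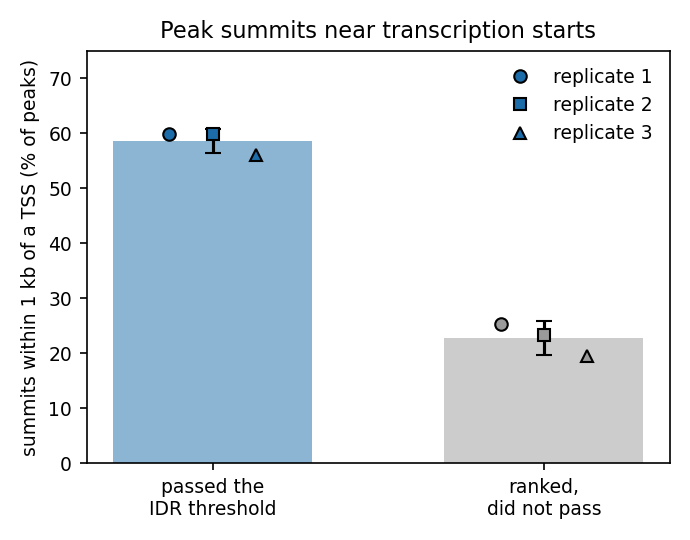
Share of peak summits within 1 kb of a TSS of a protein-coding gene, in percent of peaks, for peaks that passed the threshold and ranked peaks that did not. Bars are means of 3 replicates, at 58.6% and 22.7%, error bars are the SD and symbols are single replicates, which do not overlap between the sets.

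Peaks that passed were somewhat more frequent on the X chromosome. It held 19.3% ± 0.368 of them (SD, n = 3) and 16.6% ± 0.328 of the ranked peaks that did not pass. The difference of 2.63 ± 0.0626 points was in the same direction in 3 of 3 replicates, with odds ratios from 1.19 to 1.20 (two-sided Fisher's exact test, highest p = 0.00374 of 3 tests). Against its share of the length of the 6 chromosome arms, 17.6%, the difference was 1.67 points and no longer passed the test in every replicate (exact binomial test, highest p = 0.0991).

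The summits of peaks that passed were AT-rich. In the 101 bp centred on the summit the GC content was 34.1% ± 1.30 (SD, n = 3), against 47.0% ± 0.249 in peaks that did not pass. It was 33.9% ± 1.66 within 1 kb of a TSS and 34.4% ± 0.897 beyond it. The dip was local: in the 50-bp bin centred 175 bp from the summit, toward higher coordinates, the GC content was 43.0% ± 0.800. Peaks that did not pass were GC-rich at the summit relative to their own flanks, at 47.0% ± 0.254 in the bin centred at 25 bp and 42.6% ± 0.0827 in that at 375 bp, so that the difference between the sets has a part from each. Of all 6-mers, counted on both strands, 454 were more frequent and 905 less frequent in all 3 replicates (Fisher's exact test with Benjamini-Hochberg adjustment in each replicate). The 10 with the largest mean odds ratio consisted of A and T alone. ATATTA was found at 21.4% ± 1.91 of the summits and 5.51% ± 0.207 of the others, an odds ratio of 4.65, and was followed by AATATA, TTTAAA, TATTAA, TTAAAA, ATTTTA, TAAATA, AAATAT, ATTTAA and ATATAA, the last at 3.73. The lowest odds ratios belonged to GC-rich words: CCCGGC (0.115), CCGGAG (0.118), CCAGGA, CTCCTC, AGGACG, GGAGGA, GAGGAC, AGGAGG, CCCGGA and CAGGAG (0.170). When the background was matched on GC content, the counts fell to 21 more frequent and 18 less frequent 6-mers, among which were 4 of the 10 named higher and 5 of the 10 named lower words. The odds ratios of the named words then lay much closer to 1, at 1.12 to 1.35 for the higher (1.35 for ATATTA) and 0.344 to 0.470 for the lower. Among the words more frequent in all 3 replicates, the largest odds ratios were then those of GGCGCC (3.75), CGCCAC (2.34), CGATAG (2.17) and ACAGTG (2.07), words chosen after their values were seen.

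CAGCTG, an E-box to which achaete-scute proteins bind together with Daughterless, was rare at the summits. It occurred within 50 bp of the summit in 3.96% ± 0.534 of peaks that passed (SD, n = 3) and in 5.77% ± 0.124 of those that did not. The odds ratios ran from 0.577 to 0.730, lower in 3 of 3 replicates (two-sided Fisher's exact test, highest p = 0.00493, or 0.00792 after Benjamini-Hochberg adjustment over 15 motifs and 3 replicates). Of the 10 E-boxes of the form CANNTG, 7 including CAGCTG were less frequent in all 3 replicates and 1, the AT-rich CATATG, was more frequent, at 3.91% ± 0.365 against 2.52% ± 0.0323. Against peaks of matched GC content 0 of the 10 E-boxes were less frequent and 0 more frequent past the test in all 3 replicates (Fisher's exact test in each). The direction for CAGCTG depended on the background. Against peaks of matched GC content it was more frequent, with a background share of 2.92% ± 0.349, but the test was not passed in every replicate (Fisher's exact test, highest p = 0.0682). Against flanks of the same peaks 300 bp away, where 4.89% ± 0.417 of windows held it, the highest p was 0.808 (Fisher's exact test, which ignores the pairing).

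Beside the summit the order was reversed for CAGCTG, in windows chosen after the data were seen. From 100 to 150 bp on both sides, 7.85% ± 0.519 of the peaks that passed held CAGCTG, against 5.18% ± 0.118 of those that did not (SD, n = 3) and 4.18% ± 0.0949 of peaks with matched GC content. Odds ratios against the matched peaks were 1.76 to 2.12 (two-sided Fisher's exact test, highest p = 1.80e-09, or 1.35e-08 adjusted over 15 motifs). The excess was seen near transcription starts, at 9.50% ± 1.40 against 4.70% ± 0.273. For summits over 1 kb from a TSS it did not pass the test, at 5.57% ± 0.550 against 4.64% ± 0.0256 (Fisher's exact test, highest p = 0.704). It was not an excess of E-boxes in general. All E-boxes together were in 41.0% ± 0.107 of passing peaks and 41.3% ± 0.301 of the others. CACCTG was less frequent, at 3.05% against 4.57%, as was CAGATG, at 3.39% against 4.80% (Fisher's exact test, highest p = 0.0127 and 0.0131). Against matched peaks neither passed the test in every replicate. GAGAGAG, a GAGA element, was in these windows in 5.34% ± 0.374 of passing peaks, 1.36% ± 0.0437 of the others and 1.26% ± 0.119 of matched peaks (odds ratios against these 4.02 to 4.78), whereas at the summit itself the shares were 0.910% ± 0.296 and 1.38% ± 0.131. Its excess held beyond 1 kb of a TSS, at 4.46% ± 0.644 against 1.21% ± 0.181 in matched peaks (Fisher's exact test, highest p = 3.36e-08). The DNA replication-related element TATCGATA, a core promoter motif bound by DREF, was more frequent both at the summit, at 1.28% ± 0.160 against 0.252% ± 0.0382, and beside it, at 1.27% ± 0.189 against 0.212% ± 0.0170. Beside the summit, its excess over matched peaks was seen near transcription starts, at 2.06% ± 0.361 against 0.631% ± 0.0599. Beyond 1 kb of a TSS there was none, at 0.157% ± 0.139 against 0.166% ± 0.0362. The Zelda motif CAGGTAG and the Su(H) motif YGTGRGAA did not pass the test in every replicate at either position.

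**Figure D2:**
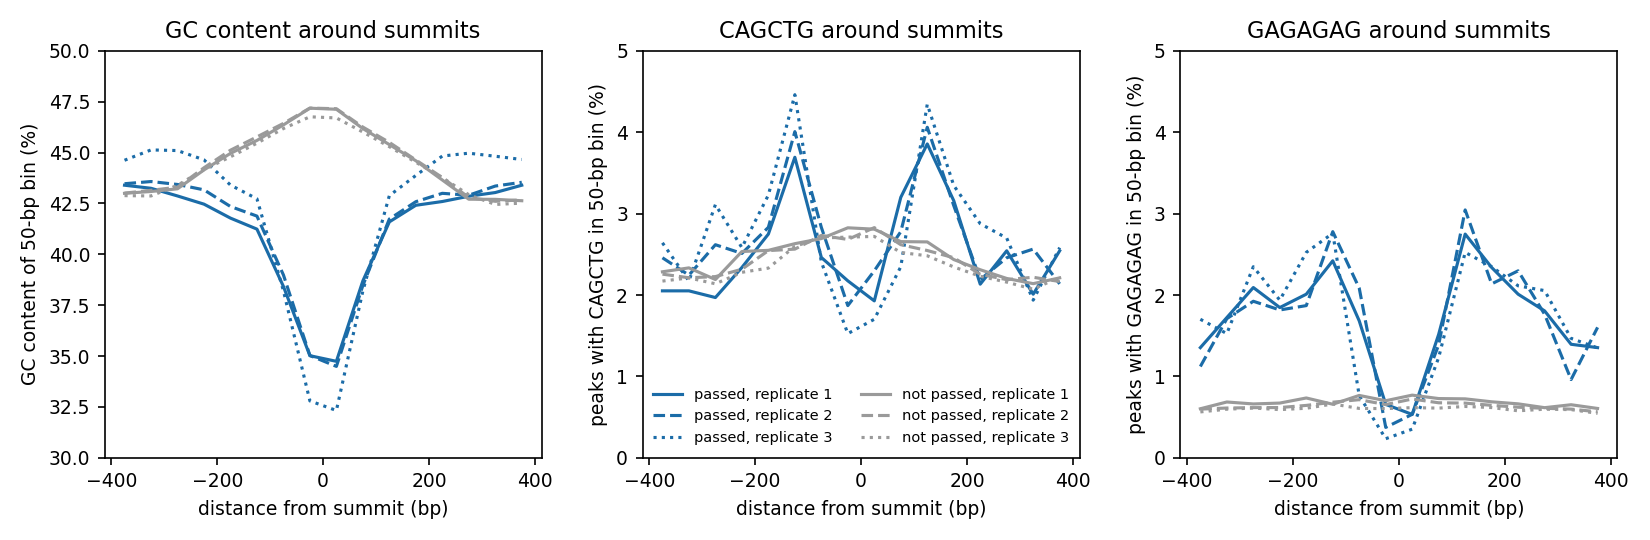
GC content (left) and the share of peaks with CAGCTG (middle) or GAGAGAG (right) in 50-bp bins against the distance from the summit in bp, for peaks that passed and ranked peaks that did not. Each line is 1 of 3 replicates, and in passing peaks the GC content is lowest at the summit and both motifs are most frequent in the bins from 100 to 150 bp on either side.

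Among 12 gene lists fixed before the data were examined, cytoplasmic ribosomal protein genes stood out. Of the 13346 protein-coding genes with any ranked peak within 1 kb of a TSS, 2243 (16.8%) had a conservative peak there. Among the ribosomal protein genes 54 of 90 did (60.0%, exact 95% interval 49.1% to 70.2%), an odds ratio of 7.58 (two-sided Fisher's exact test, p = 2.65e-20, adjusted over the 12 lists 3.18e-19). The enrichment was present in each of the 3 replicates, with 51, 40 and 39 genes. In all 3 replicates the same peak was found at 25 of the 54 genes. The strongest was 14 bp from the TSS of RpS27, in intergenic sequence (3R, 25247415 to 25247637, signal 560), followed by RpL32 (3R, 30046251 to 30046432, signal 377), RpL7 in an untranslated exon (2L, 10200969 to 10201103, signal 369), RpL34b (3R, 9401211 to 9401360, signal 366) and RpS28b (X, 9554492 to 9554657, signal 346).

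No list of neural genes passed the test against the background. The list of proneural bHLH genes also holds genes that are not proneural, such as emc, which encodes an antagonist of proneural proteins. Of its 11 genes 3 had a conservative peak: ase, emc and da, which encodes the partner Daughterless. None of these peaks recurred in all 3 replicates. Of 21 genes of neuroblast identity and asymmetric division 5 had one, namely brat, numb, insc, par-6 and aPKC. Those at brat, a growth inhibitor passed to one neuroblast daughter, and at numb, a Notch inhibitor, were found in all 3 replicates: the brat summit was in an intron 693 bp from an annotated TSS (2L, 19165076 to 19165252, signal 468), and the numb summit in an intron 172 bp from a TSS (2L, 9449496 to 9449819, signal 312). None of the 15 temporal and spatial patterning genes of neuroblasts had a peak within 1 kb, which leaves an exact 95% upper limit of 21.8%. Of 23 Notch pathway and Enhancer of split genes 4 had one: gro, the co-repressor (3R, 26042422 to 26042601, signal 503), and its neighbour E(spl)m8-HLH, a Notch target (3R, 26039974 to 26040297, signal 168), both in all 3 replicates, and neur and E(spl)m3-HLH. In replicate 3 alone 6 of the 23 had a peak (Fisher's exact test, p = 0.0213, adjusted 0.128). Sensory organ precursor genes had 2 of 9, cpo (3R, 17919180 to 17919325, signal 317, all 3 replicates) and ttk. Neuronal differentiation genes had 3 of 18, and the peak at elav, a neuronal RNA-binding protein gene, lay in an intron of the neighbouring gene arg (X, 523423 to 523547, signal 397, all 3 replicates). Glial genes had 3 of 10, among them moody, a receptor gene of the blood-brain barrier, with the summit in an intron of CG4313 (X, 2050179 to 2050383, signal 584, all 3 replicates). The lowest adjusted p among the other 11 lists was 0.549. When each peak counted for the gene of the nearest TSS at any distance, the odds ratio moved from 1.55 to 2.91 for neuroblast genes (Fisher's exact test, p = 0.0204, adjusted 0.102), from 1.41 to 3.78 for sensory organ precursor genes (adjusted 0.134), from 1.04 to 1.58 for Notch genes, from 0.990 to 2.18 for neuronal genes, from 0 to 1.18 for temporal and spatial patterning genes and from 2.12 to 3.15 for glial genes (adjusted 0.161). For the proneural list it was 1.77 in place of 1.86 (adjusted 0.458). The nearest-TSS setting was not matched on gene length or on the space around genes. With peaks counted in gene bodies, ratios to the mean of length-matched random lists were 1.12 for neuroblast, 0.892 for sensory organ precursor and 1.09 for Notch genes. They were 0.895 for neuronal, 1.17 for glial, 0.378 for patterning and 1.52 for proneural genes. None of these passed the permutation test (lowest adjusted p = 0.404).

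The lists of other tissues and of the cell cycle did not pass the test either. Cell cycle genes had 5 of 17 (CycE, CycB3, CycD, dap and Cdk1), none of them in all 3 replicates. When a gene counted with a peak anywhere in it or within 2 kb, 11 of the 17 had one, 2.18 times the mean of length-matched random lists (permutation p = 0.0040, adjusted 0.024). Mesoderm and muscle genes had 3 of 15, with the peak at the heart gene tin found in all 3 replicates (3R, 21378709 to 21378820, signal 352). Endoderm, fat body and blood genes had 3 of 11, with bowl in all 3 replicates (2L, 3771389 to 3771550, signal 364). Epidermis and trachea genes had 2 of 11. The odds ratios of these 4 lists were 2.06, 1.24, 1.86 and 1.10, with adjusted p from 0.686 to 1 (Fisher's exact test). By the nearest TSS at any distance, those of mesoderm and epidermis were 3.15 and 3.94 (Fisher's exact test, adjusted p = 0.102 for both). With lists of 9 to 23 genes, intervals of the shares were wide.

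**Figure D3:**
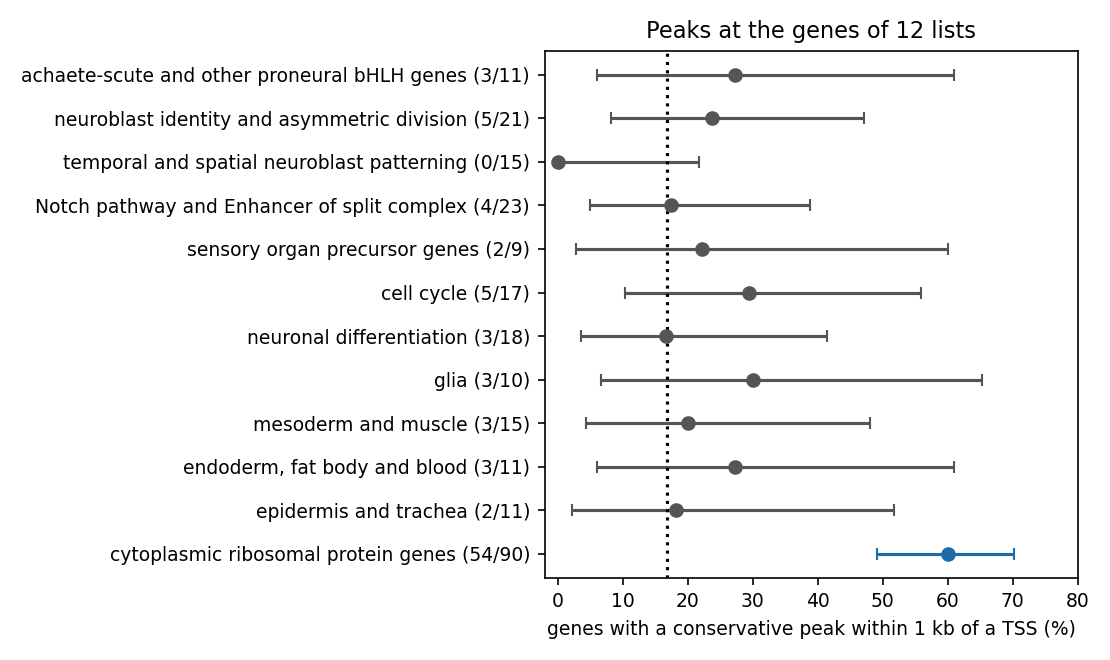
Share of the genes of each of 12 lists that have a conservative peak within 1 kb of a TSS, in percent, with exact 95% binomial intervals and the number of genes in parentheses. The dotted line is the 16.8% of background genes, ribosomal protein genes in blue are at 60.0%, and the intervals of the other lists include the line.

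In the conservative list, peaks with CAGCTG at the summit ranked lower by signal than the rest. Of the 3223 conservative peaks on the 6 arms, 150 held CAGCTG within 50 bp of the summit. Their mean rank by signal was 1936, where rank 1 is the strongest, against 1596 for the 3073 others, a difference of 340 ranks (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest they can give). The difference was 140 ranks with windows of 100 bp, 158 at a global IDR of 0.001 and 184 by the authors' score. This test used the series-wide list, so the agreement of the 3 replicates was not examined. Peaks were not matched on GC content or on distance to a TSS, so a part of these in the difference was not tested.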

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

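The test of CAGCTG as the main site and the chromosome shares with further peaks counted as passed were chosen after the results had been seen, and the windows beside the summit were chosen from the profile. The design has a single group, so no explanation that needs a comparison of groups was tested.

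Some ranked peaks reached the score of the authors' threshold but are not in the thresholded list of their replicate. There were 63 in replicate 1, 66 in replicate 2 and 183 in replicate 3. Of the 63 in replicate 1, 31 overlapped such a peak in both other replicates. The strongest of these, chosen after their values were seen, were near cbt (2L, summit 481104, signal 573 in replicate 1), Lk6 (3R, summit 11761040, signal 477), larp (3R, summit 28326609, signal 280) and trx (3R, summit 14283858, signal 246). Of the 63 and 66 in replicates 1 and 2, 55 and 51 lay on 2L or 3R and 0 on X. Of the 183 in replicate 3, 48 lay on 2L or 3R, 31 on X and 96 off the 6 arms. With these peaks counted as passed, the excess on X was 2.54 points (Fisher's exact test, highest p = 0.0210), and 3R held 22.3% ± 0.754 against 25.6% ± 0.622 (SD, n = 3, Fisher's exact test, highest p = 0.00996).

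Peaks that passed had AT-rich summits, at 34.1% GC against 47.0%. If AT-rich DNA alone made a peak wherever it lies, windows of equal GC content should hold a summit about as often far from a TSS as near it, but the rate was 5.82 times higher within 1 kb (Mantel-Haenszel rate ratio, mean of 3 replicates, range 5.18 to 6.14), which argues against it as the whole cause. A general rise of signal with AT content stays open: over 1 kb from a TSS, signal rose slightly with GC content among peaks that did not pass (Spearman's rho across peaks, mean 0.0832, range 0.0603 to 0.103) and among all ranked peaks (0.0280 to 0.0822), but the former were selected by not passing, and the rates of passing summits went the other way. Windows of 25% to 35% GC held a summit at 8.58 ± 1.28 per 1000 near a TSS and 1.54 ± 0.217 far from it, against 1.97 ± 0.860 and 0.321 ± 0.0820 at 45% to 55% (SD, n = 3). Preferences of shearing or amplification for AT-rich open chromatin also stay open, since the control's values were not used here.

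CAGCTG was rare at summits and more frequent beside them, and its share of 3.96% argues against direct binding at CAGCTG under the summit as the source of most peaks. The low share may follow from the AT-rich sequence, since against background of matched GC content it was 1.04 points higher rather than lower (range 0.822 to 1.21). The excess at 100 to 150 bp is not accounted for by GC content there, as it was 3.67 points over matched peaks. Whether other words with as many G and C bases share it stays open: CAGCTG ranked 14 by odds ratio among all 6-mers, but the windows were chosen from its own profile, and AGAGCG, GAGAGC and GAGCGA, with as many G and C bases, ranked higher. Promoter sequence as the source cannot be told apart from binding, because beyond 1 kb of a TSS the excess was 0.934 points, above 0 in 3 of 3 replicates but past the test in none (Fisher's exact test, highest p = 0.704).

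Many peaks of a replicate were missing from another. A candidate explanation is that the sites lie just under the threshold there. Of the missing peaks, a median of 58.7% over the 6 ordered pairs (range 49.6% to 73.3%) overlapped a ranked peak in the top 10% by signal of the other replicate, against 5.18% to 7.98% of the peaks that had not passed. Between 77.5% and 93.2% overlapped a ranked peak of any signal there, and why the rest overlapped none was not tested. The top 10% is wider than the 1.68% to 2.84% of ranked peaks that passed. The values therefore show that many missing sites ranked high in the other replicate, but not that they lay just under the threshold. A difference in depth between replicates stays open, since depth is unknown.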

How the results depend on the processing

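The IDR level of 0.001, the unmatched background of equal size, the counting of further peaks on X, the split of CAGCTG by distance to a TSS and the windows beside the summit were added after the data were seen. The planned IDR of 0.01 removed no peak and says nothing about stability. Over the other alternatives, 51 of 62 values of the main results kept their direction and their side of the test, or for counts stayed within 1.5 times. The 62 include the values without 1 replicate. There the calls for the TSS, X, CAGCTG and overlap could not change, since each replicate or pair had already passed. Counts of shared peaks and of called 6-mers could only rise. The 51 of 62 therefore overstate stability. Without each replicate in turn, the mean number of peaks was 1844.5 to 2158, the mean overlap 59.8% to 72.1%, the count of conservative peaks found in all remaining replicates 1112 to 1519, the difference near a TSS 35.5 to 36.6 points, that on X 2.60 to 2.66 points, that for CAGCTG -1.98 to -1.56 points and the count of called 6-mers 1395 to 1437. At an IDR of 0.001 the mean number of peaks per replicate moved from 2043 to 1276, by construction. The excess on X was 1.67 points against chromosome length and no longer passed in every replicate. For CAGCTG the difference was -1.64 points with windows of 100 bp and -0.929 points against flanks, neither past the test. It turned positive against a background matched on GC content: 1.04 points for all peaks, 1.06 for those over 1 kb from a TSS and 0.639 for those nearer, which the matching itself explains in part, since the background share fell. In windows 100 to 150 bp from the summit it was 2.66 points, and 3.67 with matching. Matching moved the count of called 6-mers from 1359 to 39, and the share of higher words among them from 33.4% to 53.8%. An unmatched background of equal size gave 1263, so the size alone does not account for the fall. With peaks counted in gene bodies and, at the same time, random lists matched on gene length in place of Fisher's exact test, the called lists went from 1 to 2, with the cell cycle added. Which of these choices matters was not separated, and the cause was not tested.

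Among single motifs, matching on GC content turned the difference for CACCTG to 0.373, GAGAGAG to 0.0869 and CAGGTAG to 0.0200 points, and windows of 100 bp turned GAGAGAG to 1.05. Of the other results, 294 of 354 values kept direction and side of the test, 23 became weaker, 2 stronger and 6 moved. The 354 include the named 6-mers without 1 replicate, which could not lose a call already held in each replicate. For gene lists the values are odds ratios, except that those for gene bodies are ratios to the mean of length-matched random lists. Neuroblast, glial and endoderm genes stayed above 1 in each setting. Values that crossed 1 were 0 for the proneural list at an IDR of 0.001, for peaks found in all 3 replicates and in replicate 3. For temporal patterning genes the nearest TSS gave 1.18. For the Notch list an IDR of 0.001 gave 0.790, a distance of 500 bp 0.863 and replicate 1 0.916. For sensory organ precursor genes 500 bp gave 0.822, gene bodies 0.892, and replicates 1 and 2 0.763 and 0.989. For the cell cycle an IDR of 0.001 gave 0.518 and peaks in all 3 replicates 0. Neuronal genes by nearest TSS gave 2.18. For mesoderm, an IDR of 0.001 gave 0.592, gene bodies 0.805, peaks in all 3 replicates 0.926, and replicates 1 and 3 0.436 and 0.651. For epidermis 500 bp gave 0.575, gene bodies 0.945, and an IDR of 0.001, peaks in all 3 replicates and replicates 2 and 3 each 0. The cause was not tested. Of 35 named genes, ase and CG11050 had a peak within 1 kb in 1 replicate and in 0 at an IDR of 0.001, E(spl)m8-HLH went from 3 replicates to 1, and Adf1, brat and cpo from 3 to 0 at 500 bp. Depth is unknown and limits how far a missing peak can be read.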

Other observations

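The lists of mitochondrial ribosomal protein and translation initiation factor genes were tested after members had been seen among the strongest peaks, and the stretches of 100 kb were examined without a plan, as were the classes of small RNA genes.

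Conservative peaks were clustered along the chromosomes. Of 1342 stretches of 100 kb, 409 held none, and the mean was 2.40. The fullest, on 3L from 700001 to 800000, held 16, and their nearest genes were emc, whose protein antagonises proneural bHLH factors, CG13895, CG13896, CG13898 and hng3. In the replicates' own lists this stretch held 13, 9 and 10 peaks. The adjoining stretch from 600001 held 14. The highest count under random placement was 9 (median of 1000 placements). Passing peaks lie near transcription starts more often than random positions do. Random placement therefore cannot separate clustering of peaks from an uneven spread of genes. Next came 12 peaks on 2L from 1600001 to 1700000, nearest to chinmo, which encodes a regulator of neuronal temporal identity, CG14352 and RFeSP, and 12 on 2R from 18300001 to 18400000, around sbb. The chromosome 4 held 2 conservative peaks, and its share of passing peaks, 0.155% ± 0.0938 (SD, n = 3), was close to that of peaks that did not pass, 0.117% ± 0.0530. On 3R the share was lower, at 21.5% ± 0.699 against 25.6% ± 0.615 (Fisher's exact test, odds ratios 0.731 to 0.842, highest p = 0.000486).

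In windows 100 to 150 bp beside the summit, 80 6-mers were more frequent and 59 less frequent than in peaks of matched GC content in all 3 replicates. The leading words were AGAGAG (odds ratio 3.09), GAGAGA (3.09), ACAGTG (2.73) and CGATAG (2.72), with adjusted p of at most 3.09e-09 (Fisher's exact test). ACAGTG was in 9.99% of passing and 3.91% of matched peaks.

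Mitochondrial ribosomal protein genes held 4 of the 20 strongest peaks within 1 kb of a TSS, counting mRpS23, which shares its peak with CenG1A. The hypothesis that the list as a whole has more peaks was not borne out by the test: 14 of 70 genes had a conservative peak, an odds ratio of 1.24 (Fisher's exact test, adjusted p = 0.629 over 4 lists). Translation initiation factor genes had 8 of 40, an odds ratio of 1.24 (Fisher's exact test, adjusted p = 0.629), among them eIF2Bbeta, which shares the Ugalt peak. In replicates 1, 2 and 3 the odds ratios were 2.04, 1.68 and 1.94 for initiation factor genes. For mitochondrial ribosomal protein genes they were 1.53, 1.48 and 1.89. None of these passed the test (Fisher's exact test, lowest p = 0.0639). Proteasome subunit genes, tested as a further ubiquitous complex, had 3 of 46, an odds ratio of 0.344 (Fisher's exact test, p = 0.0731, adjusted 0.292), and odds ratios of 0.277, 0.551 and 0.635 in the replicates. These lie under 1, against the tested excess, but not beyond their spread, since the exact 95% interval of 0.344 runs from 0.0683 to 1.08. Hox genes, tested as developmental regulators, had 2 of 8, Dfd and abd-A, an odds ratio of 1.65 (Fisher's exact test, adjusted p = 0.629). In the replicates their odds ratios were 0.872, 0 and 0. The exact 95% intervals of the other odds ratios also include 1, at 0.636 to 2.26 for mitochondrial ribosomal protein, 0.492 to 2.75 for initiation factor and 0.163 to 9.24 for Hox genes.

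A summit within 500 bp of a tRNA, snRNA or snoRNA gene was found for 0.701% ± 0.204 of peaks that passed and 0.291% ± 0.0584 of those that did not (SD, n = 3). The mean odds ratio was 2.39 and the share was higher in 3 of 3 replicates, but 1 replicate did not pass (Fisher's exact test, highest p = 0.0635). By class, snoRNA genes had shares of 0.351% ± 0.0229 and 0.123% ± 0.0315 (Fisher's exact test, highest p = 0.0283, not adjusted for the 3 classes). These rest on 8, 7 and 6 passing peaks in replicates 1, 2 and 3. Peaks were not matched on distance to a TSS of a protein-coding gene. For tRNA genes the shares were 0.242% ± 0.109 and 0.150% ± 0.0306, and for snRNA genes 0.108% ± 0.0936 and 0.0213% ± 0.000947, with 0 passing peaks in replicate 3, and the highest p was 1 for both.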
